A study of Mus musculus with 24 samples.

How the data were processed

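Müllerian duct regions of 12 female mouse embryos were analysed, 3 for each combination of genotype (wild-type or Wnt7a-null) and stage (E13.5 or E14.5), with an MDE and an MDM library from each embryo. Per the labels' protocols, tissue was fixed in paraformaldehyde, embedded in paraffin and sectioned, 1 section per sample was placed on a single slide, and barcodes released from hybridised DNA probes by ultraviolet light were sequenced; the series' design text says that regions were chosen by laminin immunofluorescence. The deposited values are whole-number counts per probe, not normalised, made with the GeoMx NGS Pipeline 2.3.5, per the file headers. In every file they sum to less than the aligned reads, so reads were collapsed before counting, by a rule not given in the sources used here. A genome build, GRCm38.p6, is named in the submitters' processing notes. Probes with no counts are not listed in a file and were set to 0; 19862 to 20175 of the 20175 panel probes were listed per library.

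Groups, replicate numbers and embryos came from the titles, in which the same number joins the MDE and MDM library of an embryo. None of the 20175 probe identifiers matched the gene table used here (0 matched). Gene names and the identity of negative control probes were therefore not used here, and the planned check of Wnt7a and Hoxa13, the gene list tests and the filter at the limit of quantitation were not run. Named probes followed the rule set for this case: per comparison at most 2 identifiers that rose and 2 that fell, with the lowest p.

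Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr (minimum count 10, minimum total 15), a robust quasi-likelihood fit and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. One fit held the 12 MDE libraries and another the 12 MDM libraries, each with a mean per genotype and stage, and gave the null against wild-type difference at each stage and on average, the stage difference per genotype, and their interaction. The region fit held all 24 libraries with the embryo as a block and gave the region differences and their interaction with genotype. Levels are TMM-scaled CPM (counts relative to the library total) as mean ± SD over 3 embryos. The SE of an edgeR log2 fold change was derived from its test, as its size over the square root of the F statistic. In limma the moderated t was used in the same way. The design, the main tests, the naming rule and the first set of alternatives were fixed before the data were examined.

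Alternatives set at the outset were upper-quartile scaling at the 75th percentile, DESeq2 1.42.0, no low-count filter, a filter at 20 counts, the replicate number as a block, only the 6 libraries compared, limma-voom (limma 3.58.1) with the embryo as a random block, the region fit without the embryo block, and leaving out each library or embryo in turn. Alternatives chosen after seeing the data were the library's signal contrast as a covariate, thinning of counts to the lowest total of a fit or of MDM libraries to the total of the embryo's MDE library, and limma on background-subtracted signal. Signal contrast is the log2 share of counts on the 1009 brightest probes (5% of the panel). Background was taken per library as the mean of the 5044 dimmest probes (25%), on probes averaging at least 1.5 times background, with a floor at 0.25 of background. The same probes were also tested without subtraction, with 0.25 of background added to each value. Both limma fits centred each library on the median of these probes. Exact and permutation tests used scipy 1.17.1 and numpy 2.4.6 in Python 3.11.15, and figures matplotlib 3.10.9.

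The steps were tested on simulated counts with known fold changes. For the E14.5 genotype comparison in MDE, 31% of probes changed 2-fold and 89% of those changed 4-fold were recovered, with 3 false calls among 16014 tested; in MDM both were 100%, with 10 false calls among 20175. For the wild-type region comparison 77% and 100% were recovered, with 12 false calls among 20175. After background subtraction 6% and 53% were recovered for MDE and 46% and 56% for MDM, against 9% and 60% and 47% and 56% by limma on the same probes without it. Of each 100 planted probes only 58 and 62 in MDE and 47 and 56 in MDM were bright enough to be tested in these limma fits. Those not tested count as missed in the percentages. These simulations gave all libraries 1 contrast. In counts simulated with no probe changed, but with the background share measured in each library, edgeR called 12 probes for MDE and 2357 for MDM at E14.5 (731 higher and 1626 lower in null) and 0 at E13.5, and limma after subtraction called 0. The last result was largely fixed in advance, since the background subtracted was the one put in. That simulation used a coefficient of variation of 0.05, below the 0.125 and 0.0873 of the MDE and MDM fits, and lower noise gives more calls.

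No pair of files was identical. Over probes with at least 20 summed counts, all 24 within-group pairs of libraries differed by more than counting noise, with chi-square per degree of freedom from 1.02 (wild-type E14.5 MDE replicates 2 and 3) to 7.16, and the former pair reached 1.20 over its bright probes (chi-square p = 8.60e-06). The labels call the 12 embryos biological replicates. Deviations from the group mean went together in the MDE and MDM libraries of the same embryo (median r = 0.183 across probes, 8 of 12 above 0.1) and less so between embryos of a group (median r = −0.0682); the region fits keep the embryo as a block. All sections lay on 1 slide, and the sources used here give no sequencing batch.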

Results

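The transcriptome of the Müllerian ducts, the paired embryonic tubes that give rise to the oviducts, uterus and upper vagina, was profiled in female mouse embryos that were wild-type or lacked Wnt7a, which encodes a secreted Wnt ligand. Embryos were taken at E13.5 (E, embryonic day), before the ducts fuse, and at E14.5, when the ducts lie side by side at the midline and the basement membrane between them begins to break down. In each embryo the duct epithelium (MDE) and the mesenchyme beside it (MDM) were captured as separate regions on the GeoMx platform, in which barcodes released by ultraviolet light from hybridised probes are sequenced. Laminin staining guided the choice of regions. The 24 libraries came from 12 embryos and fell into 8 groups of 3, defined by genotype, stage and region. Each library held counts for a panel of 20175 probes. The probes carry numeric identifiers that were not paired with gene names here, so individual probes are reported by identifier, and the level of Wnt7a itself, the check on the genotype labels, is not reported.

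Depth differed strongly between the regions. Total counts ranged from 139017 to 2618342 in the 12 MDE libraries, with a median of 247934, and from 1039606 to 12379529 in the 12 MDM libraries. One MDE library, null E14.5 replicate 2, stood apart with 2618342 counts from 62991623 aligned reads, or 24.1 aligned reads per count. The other 11 MDE libraries had at most 619233 counts and 2.07 to 2.38 aligned reads per count, against 21.1 to 26.8 in MDM. Depth also differed between genotypes in MDM, with 3707769 to 12379529 counts in null and 1944958 to 3625081 in wild-type at E14.5 (n = 3 each), and 2481026 to 3275877 against 1039606 to 1539942 at E13.5. In E14.5 MDE the null libraries, at 305606 to 2618342 counts, also lay above the wild-type libraries, at 175461 to 298133, while at E13.5 the MDE ranges overlapped (139017 to 365215 in null and 144049 to 252679 in wild-type). The median probe had 5 to 112 counts in an MDE library and 37 to 546 in an MDM library, so counting error limits the dim probes of the epithelium most.

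**Figure D1:**
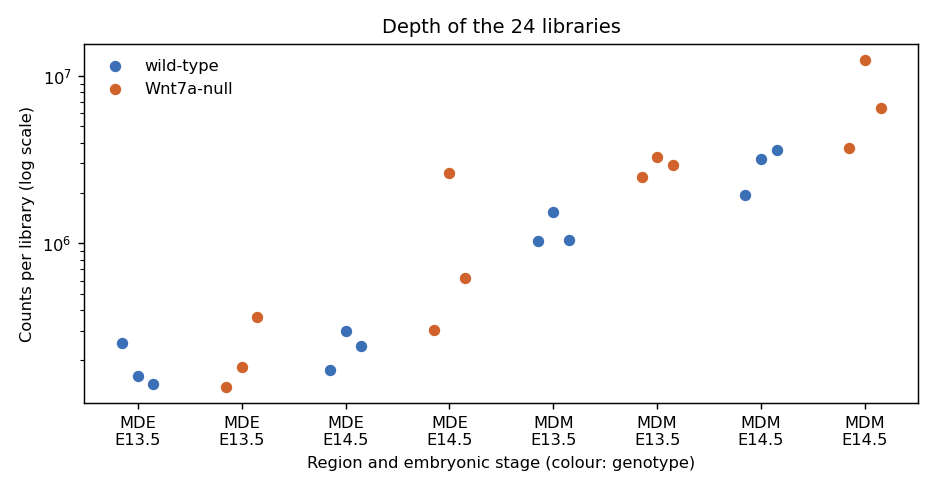
Total counts per library (log axis) by region, stage and genotype; each point is 1 library and 3 libraries form each group. MDE libraries lie between 139017 and 619233 counts except 1 null E14.5 library at 2618342, and MDM libraries lie between 1039606 and 12379529.

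Libraries also differed in signal contrast, measured as the share of all counts that fell on the 1009 brightest probes, 5% of the panel. At E14.5 this share was 17.5% ± 1.78 in null and 27.7% ± 1.21 in wild-type MDE, and 16.1% ± 2.27 in null and 25.7% ± 0.771 in wild-type MDM (SD, n = 3 each). Every null library at E14.5 lay below every wild-type library of its region; the exact two-sided permutation test gave p = 0.1 in each region, the smallest that 3 against 3 allows, and 0.2 after adjustment over 4 comparisons. At E13.5 the shares were 22.8% ± 4.39 and 22.9% ± 3.93 in MDE (exact p = 1) and 21.3% ± 3.10 and 21.8% ± 3.99 in MDM (exact p = 0.9). Within embryos the share was higher in MDE than in MDM in 11 of 12, by 1.51 percentage points on average (SD 0.742, permutation p = 0.000977). The first principal component of 2212 bright probes held 50.7% of the variance. It went with signal contrast, with an absolute r of 0.941 to the log2 share over the 24 libraries, though both rest on bright probes. The second held 11.4% and placed all 12 MDE libraries above every MDM library, null E14.5 replicate 2 included. The dimmest 25% of probes, taken as background, averaged 25.6 to 30.2 CPM (counts scaled by TMM to the library total) across the 8 groups. Probes under 1.5 times the background of a compared group are named below as near it, where a fold change includes background signal, and for probes at or below it levels are given without a fold change.

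**Figure D2:**
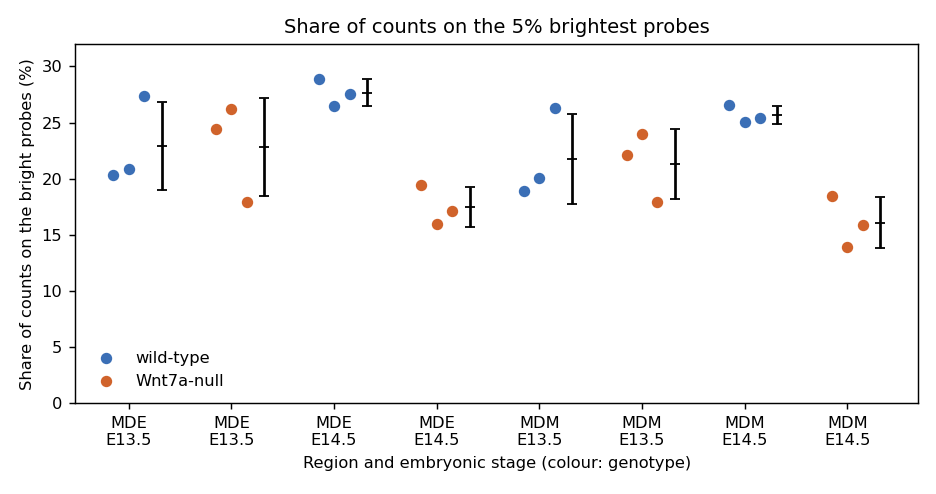
Percent of each library's counts on the 1009 brightest probes, by region, stage and genotype; each point is 1 library, with the group mean and SD beside it. Null and wild-type libraries overlap at E13.5 and separate at E14.5, with means of 17.5% against 27.7% in MDE and 16.1% against 25.7% in MDM.

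Before the ducts fuse, the epithelium of null embryos differed from wild-type in 1 of 14758 probes tested. RTS0066123 stood at 540 ± 347 CPM in null and 2000 ± 504 CPM in wild-type MDE (SD, n = 3 each), a log2 fold change of −1.87 (SE 0.322, adjusted p = 9.27e-05 by edgeR's quasi-likelihood test). In the mesenchyme of the same embryos this probe stood at 417 ± 282 against 1714 ± 422 CPM, a log2 difference of −2.03 (SE 0.450) that did not pass (adjusted p = 0.9998). No probe of 20175 passed in E13.5 MDM, where 768 had an unadjusted p under 0.05; DESeq2 called 0 with 630 unadjusted, and limma-voom called 2. In MDE, 634 probes had an unadjusted p under 0.05, DESeq2 called 0 with 252 unadjusted, and limma-voom called 2.

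The E13.5 epithelial call depended on single libraries. Without null E13.5 replicate 1 the log2 fold change of RTS0066123 was −1.49 (adjusted p = 0.307) and edgeR called 0 probes with 811 unadjusted, and without null E13.5 replicate 3 it called 6. In MDM the count rose from 0 to 1 without null E13.5 replicate 2, with RTS0066123 at adjusted p = 0.0190.

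At the stage of apposition, null and wild-type embryos differed broadly in both compartments. In MDE, 797 of 14758 probes passed, 681 lower and 116 higher in null, and in MDM 6001 of 20175 passed, 3558 lower and 2443 higher. The difference followed probe brightness: the brightest of 5 equal classes of probes had a median log2 fold change of −0.44 in MDE and −0.41 in MDM, the dimmest class 0.22 and 0.13, and calls in the brightest class of MDE probes numbered 605 lower and 9 higher in null. At E13.5 the brightest class had medians of −0.02 in MDE and 0.02 in MDM. Calls over 2-fold numbered 329 lower and 104 higher in MDE, and 372 lower and 0 higher in MDM. The counts depended on depth, which differed between the genotypes: thinned to the lowest total, 190 probes passed in MDE (42 higher, of 3854 tested) and 2375 in MDM (533 higher), and MDM thinned to the embryo's MDE total gave 1021. Limma-voom gave 1338 in MDE and 2689 in MDM.

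**Figure D3:**
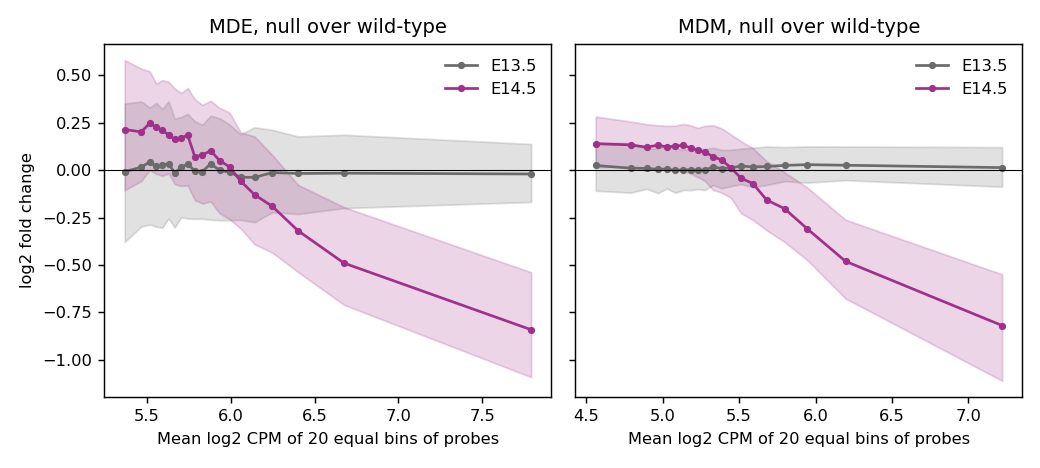
Log2 fold change of null over wild-type against mean log2 CPM in 20 equal bins of probes, for MDE and MDM; lines are medians and bands the middle 50% of probes in a bin. At E14.5 the median falls from 0.21 in the dimmest bin to −0.84 in the brightest in MDE and from 0.14 to −0.82 in MDM, while at E13.5 the brightest bins lie at −0.02 and 0.01.

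In E14.5 epithelium the lowest p-values among falling probes belonged to RTS0073440 and RTS0081238. RTS0073440 measured 80.9 ± 5.04 CPM in null and 301 ± 21.8 in wild-type MDE (n = 3 each), a log2 fold change of −1.83 (SE 0.274, adjusted p = 3.10e-07). RTS0081238 measured 172 ± 100 against 752 ± 175 CPM, −1.98 on the log2 scale (SE 0.302, adjusted p = 4.23e-07). Among rising probes RTS0065248 measured 75.5 ± 14.2 against 23.8 ± 10.0 CPM (adjusted p = 0.00101) and RTS0081602 42.7 ± 6.89 against 14.0 ± 5.02 CPM (adjusted p = 0.00154), both below background in wild-type. The call of RTS0081602 ended without wild-type E14.5 replicate 3 (adjusted p = 0.0552). With the library's signal contrast as a covariate, edgeR called 0 MDE probes with 845 unadjusted, and all 4 named calls ended, with RTS0073440 at −1.96 (SE 0.433, adjusted p = 0.0649). The MDE count was 381 without wild-type E14.5 replicate 1, 496 without replicate 2 and 419 without replicate 3, and 509 without null E14.5 replicate 2 and 316 without replicate 3. Upper-quartile scaling moved the median log2 fold change of all probes from 0.04 to 0.18 and the split of calls to 269 higher and 483 lower. DESeq2, which differs in scaling, spread estimate and test, gave 1 higher and 726 lower.

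In E14.5 mesenchyme the probe with the lowest p was RTS0068500, at 42.7 ± 2.64 CPM in null and 184 ± 62.3 in wild-type MDM (n = 3 each), a log2 fold change of −2.15 (SE 0.164, adjusted p = 3.21e-14), with the null level near background at 1.41 times; on background-subtracted signal it was −3.06. RTS0062148 followed with 54.5 ± 4.57 against 177 ± 21.9 CPM and −1.72 (SE 0.161, adjusted p = 7.81e-12). Among probes called higher, RTS0080940 measured 27.97 ± 2.46 in null and 14.8 ± 1.68 CPM in wild-type (adjusted p = 4.75e-06), below background in both. RTS0079323 measured 48.0 ± 1.09 against 28.8 ± 3.02 CPM, a log2 change of 0.70 (SE 0.112, adjusted p = 4.82e-06) with wild-type near background. With signal contrast as a covariate 5 MDM probes passed; RTS0062148 was among those still called (−1.35, SE 0.224, adjusted p = 0.00206), and RTS0068500 was not (−2.02, SE 0.463, adjusted p = 0.261), nor were the 2 probes called higher. The MDM count was 3966 without null E14.5 replicate 2 and 3975 without replicate 3. Upper-quartile scaling moved the median of all MDM probes from 0.03 to 0.13 and turned the split to 5155 higher and 2717 lower, so the balance of directions in MDM depends on the scaling, and DESeq2 gave 1413 higher and 3492 lower.

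**Figure D4:**
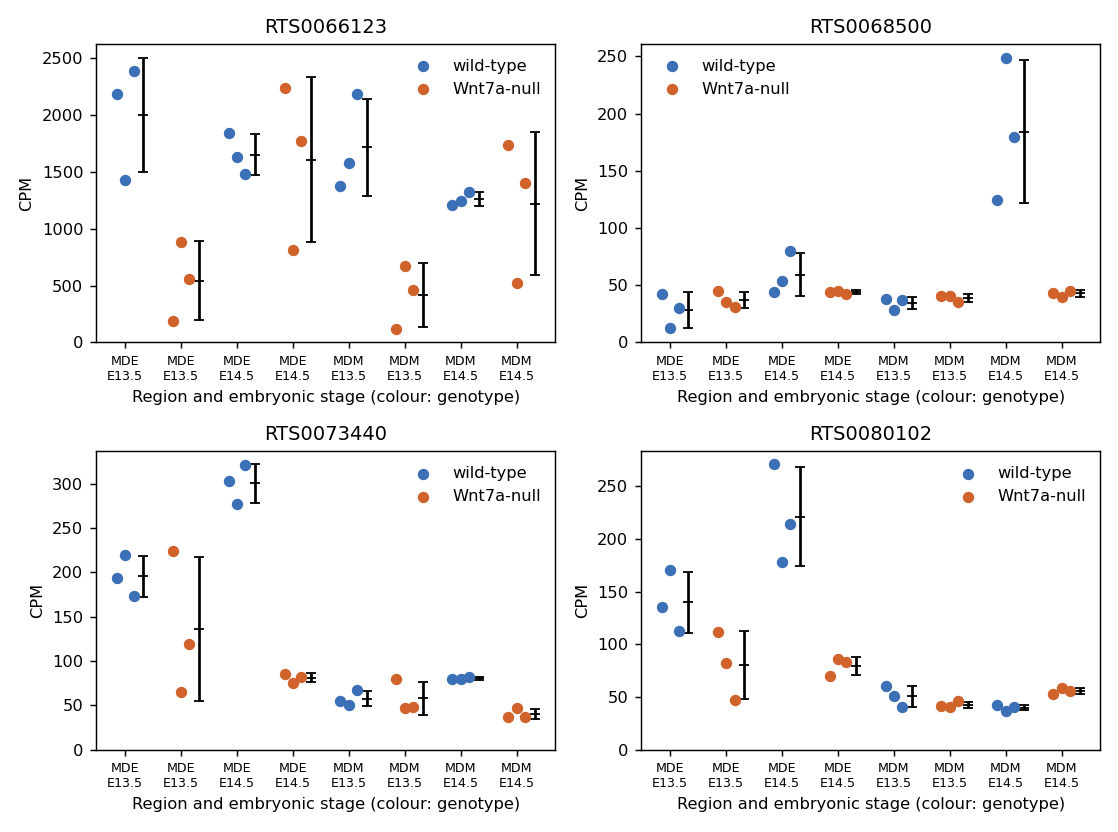
CPM of named probes in every group of region, stage and genotype; each point is 1 library, with the group mean and SD beside it. RTS0066123 is lower in E13.5 null embryos in both regions (540 against 2000 in MDE), and RTS0068500 is high in wild-type E14.5 MDM (184) and lies at 34.5 to 42.7 in the other MDM groups.

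Many of the probes lower in null embryos at E14.5 were shared by both regions of the same embryos. Of 14758 probes tested in both, 681 were lower in MDE and 3422 in MDM, and 628 were lower in both, where independent lists would share 158. The 158 takes no account of brightness. Lower calls gathered in the brightest class of each region's fit, 605 of 681 in MDE and 2278 of 3558 in MDM, so lists tied only to brightness could share more. For higher probes 60 were shared between 116 and 1711, against 13.4 for independent lists. The regions come from the same embryos, so these overlaps also hold whatever varies from embryo to embryo.

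Averaged over both stages, 55 probes passed between null and wild-type epithelium, 6 higher and 49 lower in null, and 1057 passed in mesenchyme, 181 higher and 876 lower. Of 100 splits of the libraries, the real one included, 5 gave as many calls in MDE (434 in the highest other) and 6 in MDM (3817), so chance is not excluded for these counts. RTS0073440 fell by 1.21 (SE 0.208, adjusted p = 8.25e-05) and RTS0080102 by 1.15 (SE 0.211, adjusted p = 0.000340) in MDE. In MDM RTS0062148 fell by 1.09 (SE 0.123, adjusted p = 2.11e-08) and RTS0071848 by 0.86 (SE 0.102, adjusted p = 6.05e-08), the latter near background in E14.5 null. The lowest p among probes called higher in MDM belonged to RTS0078989, below background in wild-type (38.9 ± 2.45 in null against 24.3 ± 2.64 CPM at E14.5, 32.4 ± 7.26 against 23.2 ± 5.71 at E13.5), and RTS0080928, below it in every MDM group (29.4 ± 2.76 against 18.2 ± 2.45 CPM and 24.8 ± 4.09 against 15.4 ± 4.56), with adjusted p = 0.00217 each. The epithelial probes with the lowest p among those called higher, RTS0079734 (adjusted p = 0.0250) and RTS0075465 (adjusted p = 0.0341), were below background in wild-type, at 21.7 ± 9.29 and 20.9 ± 1.72 CPM at E14.5, and lost their calls in 7 and 8 of 12 fits that each left out 1 library.

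These averages were also fitted with signal contrast as a covariate and without single libraries. With the covariate 2 MDE and 8 MDM probes passed, RTS0073440, RTS0062148 and RTS0071848 among them. RTS0080102 was no longer called, at −1.01 (SE 0.285, adjusted p = 0.653) against −1.15 (SE 0.211) before, so that its call ended mainly because the error grew. RTS0078989 and RTS0080928 were not called either (adjusted p = 0.660 and 0.605). The MDE count of 55 became 21 without wild-type E13.5 replicate 3, 89, 110 and 10 without null E13.5 replicates 1, 2 and 3, 6, 24 and 3 without wild-type E14.5 replicates 1, 2 and 3, and 12 without null E14.5 replicate 3. The MDM count of 1057 became 275 without wild-type E13.5 replicate 3, 2133 and 579 without null E13.5 replicates 2 and 3, 473, 696 and 622 without wild-type E14.5 replicates 1, 2 and 3, and 279 without null E14.5 replicate 3. DESeq2 called 287 in MDE (0 higher) and 1704 in MDM (77 higher), limma-voom called 484 in MDE, and upper-quartile scaling split the MDM calls into 421 higher and 773 lower. Thinned to the lowest total, 30 MDE and 625 MDM probes passed.

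Between E13.5 and E14.5 wild-type epithelium changed in 21 probes, 18 of them higher at E14.5, and wild-type mesenchyme in 61, 54 of them higher. The clearest changes were rises in RTS0068500 in mesenchyme, from 34.5 ± 5.40 CPM, near background, to 184 ± 62.3 and by 2.47 on the log2 scale (SE 0.202, adjusted p = 6.09e-13), and in RTS0067100 in epithelium, from 61.9 ± 43.6 to 263 ± 74.8 CPM and by 2.15 (SE 0.328, adjusted p = 7.78e-07). RTS0063083 rose in MDE from 62.7 ± 17.6 to 230 ± 73.6 CPM, by 1.96 (SE 0.315, adjusted p = 3.64e-06), and RTS0069528 rose in MDM from 44.0 ± 6.64 to 104 ± 10.7 CPM, by 1.28 (SE 0.165, adjusted p = 1.35e-06). These 4 rises passed in each fit that left out 1 of the 6 libraries and with signal contrast as a covariate; RTS0067100 lost its call on background-subtracted signal (adjusted p = 0.273) and RTS0069528 with MDM thinned to the depth of MDE (adjusted p = 0.209).

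The falling probes of wild-type embryos were less secure. RTS0068506 fell by 1.58 in MDE (SE 0.376, adjusted p = 0.0305) and RTS0071702 by 1.57 (SE 0.385, adjusted p = 0.0381), and each lay near background at E14.5 and lost its call in 5 of 6 fits that left out a library. In MDM RTS0068711 fell by 0.78 (SE 0.159, adjusted p = 0.00875), to a level near background, and RTS0066867 by 0.94 (SE 0.204, adjusted p = 0.0153), with calls lost in 3 and 4 of 6 such fits. The MDE count of 21 became 3 and 4 without wild-type E13.5 replicates 1 and 2, and 9, 4 and 4 without wild-type E14.5 replicates 1, 2 and 3. The MDM count of 61 became 9, 8 and 190 without wild-type E13.5 replicates 1, 2 and 3, and 38, 18 and 15 without wild-type E14.5 replicates 1, 2 and 3.

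In null embryos 288 MDE probes passed over the same interval, 265 of them lower at E14.5, and 3619 MDM probes passed, 2769 of them lower. RTS0068976 fell in null MDE from 407 ± 228 to 87.8 ± 20.1 CPM, by 2.18 on the log2 scale (SE 0.281, adjusted p = 1.38e-10), and RTS0068983 fell from 392 ± 135 to 85.1 ± 7.62 CPM, by 2.08 (SE 0.297, adjusted p = 1.57e-08). In null MDM RTS0072046 fell from 285 ± 52.8 to 60.05 ± 4.43 CPM, by 2.27 (SE 0.246, adjusted p = 2.39e-09), and RTS0066867 from 171 ± 20.9 to 47.6 ± 5.88 CPM, by 1.87 (SE 0.197, adjusted p = 1.74e-09). These 4 falls passed in every alternative run, the contrast covariate included.

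Among probes that rose in null embryos, RTS0066123 rose in MDE by 1.61 (SE 0.318, adjusted p = 0.000306), from its low E13.5 level to 1607 ± 724 CPM, and RTS0074399 was higher at E14.5 (57.2 ± 19.4 against 14.6 ± 8.13 CPM, adjusted p = 0.00272), from below background. The rise of RTS0066123 was not called without null E13.5 replicate 1 (adjusted p = 0.125) and the call of RTS0074399 ended without null E13.5 replicate 3 (adjusted p = 0.0895). In MDM RTS0079800 and RTS0072062 rose by 0.59 and 0.60 (adjusted p = 0.000101 and 0.000149), the latter from near background. With the contrast covariate 40 MDE and 516 MDM probes passed, and RTS0066123 (1.89, SE 0.557, adjusted p = 0.422) and RTS0072062 (0.37, SE 0.160, adjusted p = 0.228) were not among them. Thinned to the lowest total, 88 MDE and 1477 MDM probes passed, and limma-voom called 658 and 1373. The MDE count of 288 became 116, 88 and 575 without null E13.5 replicates 1, 2 and 3, and 90 without null E14.5 replicate 3; the MDM count of 3619 became 1770 without null E13.5 replicate 2 and 1970 without null E14.5 replicate 3. Upper-quartile scaling moved the median of all probes to 0.16 in MDE and 0.14 in MDM and the splits to 70 higher with 165 lower and 3417 higher with 2111 lower, while DESeq2 gave 288 higher and 3000 lower in MDM, so the balance of directions in null MDM depends on the scaling.

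The interaction of genotype and stage was tested in each region. In MDE 45 probes passed, 4 with a genotype difference more positive at E14.5 than at E13.5 and 41 more negative, and in MDM 2080 passed, 404 more positive and 1676 more negative. In each region 5 of 100 splits of the libraries gave as many calls, the real one included, with 1119 in MDE and 6569 in MDM as the highest of the others, so chance is not excluded. RTS0068500 led the mesenchymal list at −2.36 (SE 0.274, adjusted p = 1.82e-07). In null MDM it stood at 38.8 ± 3.36 CPM at E13.5 and 42.7 ± 2.64 at E14.5, near background at both stages, as it was in E13.5 wild-type MDM. RTS0076416 followed (adjusted p = 4.68e-05), with 28.6 ± 3.68 CPM in null, below background, and 54.8 ± 1.39 in wild-type at E14.5. At E13.5 it had 49.97 ± 5.59 in null against 40.7 ± 6.91 in wild-type, the latter near background. RTS0079067 and RTS0065231 led the positive side at 0.95 and 0.89 (adjusted p = 0.00148 and 0.00237), both near background in E13.5 null and E14.5 wild-type MDM.

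In MDE the interaction of RTS0071705 was −2.17 (SE 0.415, adjusted p = 0.00243), with 131 ± 27.8 CPM in null and 459 ± 35.8 in wild-type at E14.5 and 479 ± 155 against 347 ± 130 at E13.5. RTS0062727, near background in E14.5 null, had −2.02 (SE 0.419, adjusted p = 0.0108) and RTS0066123 1.89 (SE 0.440, adjusted p = 0.0194). RTS0081602 passed as well (adjusted p = 0.0353), below background in E14.5 wild-type, and these 4 calls were lost in 4, 3, 8 and 10 of 12 fits that left out 1 library. With signal contrast as a covariate edgeR called 0 probes in either region, with 834 unadjusted in MDE and 1830 in MDM, and RTS0068500 was at −2.23 (SE 0.550, adjusted p = 0.301). Thinned to the lowest total, 26 MDE and 971 MDM probes passed. Upper-quartile scaling moved the median of all probes to 0.15 in MDE and 0.12 in MDM, and split the MDM calls into 994 higher and 1299 lower. The MDE count of 45 became 0, 0 and 221 without wild-type E13.5 replicates 1, 2 and 3 (1348 and 1577 unadjusted where 0), 5, 1 and 394 without null E13.5 replicates 1, 2 and 3, 2, 6 and 2 without wild-type E14.5 replicates 1, 2 and 3, and 2, 85 and 1 without null E14.5 replicates 1, 2 and 3. The MDM count of 2080 became 735, 720 and 3234 without wild-type E13.5 replicates 1, 2 and 3, 999 and 3530 without null E13.5 replicates 2 and 3, 1258 and 1362 without wild-type E14.5 replicates 1 and 3, and 979 without null E14.5 replicate 3.

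Epithelium and mesenchyme were set against each other within embryos, with both stages averaged. In wild-type embryos 676 of 20175 probes differed, 449 higher in MDE and 227 higher in MDM, and in null embryos 644 differed, 459 higher in MDE and 185 higher in MDM. Depth went with region: 11 of the 12 MDE libraries had 2.07 to 2.38 aligned reads per count, against 21.1 to 26.8 in MDM. A part of these differences may therefore come from depth. RTS0068983 was higher in wild-type MDE by 1.86 on the log2 scale (SE 0.109, adjusted p = 1.39e-44) and RTS0062328 by 1.95 (SE 0.126, adjusted p = 9.79e-39). RTS0064427 was lower in MDE by a log2 change of −1.91 (SE 0.117, adjusted p = 8.29e-42) and RTS0064438 by −1.74 (SE 0.138, adjusted p = 1.04e-27). The first 2 were higher in MDE in 12 of 12 embryos and the other 2 in 0 of 12.

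In null embryos RTS0066019 was higher in MDE by 1.32 (SE 0.0826, adjusted p = 1.97e-40) and RTS0062328 by 1.44 (SE 0.103, adjusted p = 1.60e-32), while RTS0064427 was lower by −1.55 (SE 0.101, adjusted p = 3.16e-38) and RTS0068462 by −1.36 (SE 0.123, adjusted p = 2.53e-21). RTS0066019 was higher in MDE in 12 of 12 embryos and RTS0068462 in 0 of 12, and all 8 of these region differences passed in every alternative run. The fit of both regions assumes that they vary alike, although the coefficient of variation was 0.125 in the MDE fit and 0.0873 in the MDM fit, so its p-values may be too small. The 0.0516 of the joint fit cannot be set against these, since that fit takes out differences between embryos. Limma-voom called 531 and 299. The null count was 420 without null E13.5 replicate 2 and 336 without null E14.5 replicate 2. Upper-quartile scaling moved the median of all probes from −0.02 to −0.16 in wild-type and turned the splits to 221 higher and 507 lower in wild-type and 209 and 393 in null, and DESeq2 gave 384 and 82 in null, so the balance of directions between the regions depends on the scaling. With signal contrast as a covariate 187 and 33 probes passed, and 246 and 104 when thinned to the lowest total.

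The region difference depended on genotype for 16 probes, 4 with a more positive and 12 with a more negative MDE minus MDM difference in null. RTS0080102 led at −1.32 (SE 0.182, adjusted p = 4.02e-08): in MDE it stood at 79.6 ± 8.64 CPM in null and 221 ± 47.3 in wild-type at E14.5 and at 80.3 ± 32.7 against 140 ± 28.9 at E13.5, and in MDM at 55.6 ± 3.06 against 39.9 ± 2.72 at E14.5 and 42.5 ± 2.99 against 50.7 ± 10.1 at E13.5 (n = 3 each). RTS0069637 had −1.05 (SE 0.195, adjusted p = 0.00150), with 68.5 ± 15.5 CPM in null and 201 ± 32.01 in wild-type MDE at E14.5 and 83.4 ± 33.7 against 92.1 ± 33.8 at E13.5. On the positive side stood RTS0081252 at 1.13 (SE 0.235, adjusted p = 0.00789) and RTS0070870 at 1.18 (SE 0.267, adjusted p = 0.0210). RTS0070870 in E14.5 MDE, RTS0080102 in wild-type E14.5 MDM and RTS0069637 in all MDM groups lay near background. With signal contrast as a covariate 16 probes passed, 15 of them among the first 16, and RTS0080102 had −1.39 (adjusted p = 1.24e-08); thinned to the lowest depth it had −0.91 (adjusted p = 0.884). The count was 8 without wild-type E13.5 replicate 3, 2 without null E13.5 replicate 3, 10 without wild-type E14.5 replicate 3 and 9 without null E14.5 replicate 2. DESeq2 called 1 (lower) and limma-voom 3, and upper-quartile scaling gave 6 higher and 10 lower.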

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

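The tests of signal contrast, an equal added background, depth and single embryos were chosen after the differences had been seen, while the counts of other splits of the libraries were planned. What drew attention here was that a contrast differed between groups, as tested by an interaction term.

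The difference between null and wild-type embryos depended on stage for 45 probes in MDE and 2080 in MDM. Among 100 splits drawn with the real one, 5 gave as many calls in MDE and 5 in MDM, with 1119 and 6569 as the highest of the other splits, so chance is not excluded for either count. Splits were drawn within each stage, so a split can keep the real E14.5 grouping and carry its difference. A split with several times the real count therefore need not come from chance alone. The same holds for the splits of the averages over both stages. In MDE the interaction was 1.89 for RTS0066123, 2.45 for RTS0081602, −2.17 for RTS0071705 and −2.02 for RTS0062727. In MDM it was 0.95 for RTS0079067, 0.89 for RTS0065231, −2.36 for RTS0068500 and −1.28 for RTS0076416. RTS0081602 in E14.5 wild-type MDE and RTS0076416 in E14.5 null MDM lay below background, so the size of their interaction is not a measured one. The MDE count ranged from 0 without wild-type E13.5 replicate 1 or 2 (1348 and 1577 unadjusted) to 394 without null E13.5 replicate 3, with every left-out library moving it by over 1.5 times.

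The region difference depended on genotype for 16 probes, and 2 of 100 splits gave as many, with 23 as the highest other. Chance is excluded at 0.05 only for this edgeR count and without adjustment over the 15 counts. The count was 2 without null E13.5 replicate 3, 1 with DESeq2, and 3 with limma-voom, without the embryo block or thinned to the lowest total. The interaction was 1.13 for RTS0081252, 1.18 for RTS0070870, −1.32 for RTS0080102 and −1.05 for RTS0069637. For RTS0080102 the call held in 21 of 22 alternatives, with adjusted p from 1.21e-08 to 0.884, the latter after thinning to the lowest depth.

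The stage dependence goes with a broad difference at E14.5, in which bright probes were lower and dim probes higher in null embryos. An equal background added to every probe is argued against as the whole cause. In limma its subtraction left the probes called lower with a median log2 fold change of −1.08 (SE 0.367) in MDE and −0.69 (SE 0.228) in MDM. These are 122% and 210% of the −0.89 and −0.33 by limma without it, and 109% and 126% of the −0.99 and −0.55 by edgeR. Limma without subtraction had 0.25 of background added to each value and each library centred on these probes. In MDM it lay above edgeR in both directions, at −0.33 against −0.55 for lower and 0.50 against 0.38 for higher probes. The 210% therefore also holds these steps. A part from background stays open, since subtraction also raised the median size of planted 2-fold changes from 0.91 to 1.83 in MDE and from 0.90 to 1.93 in MDM. Counts simulated with no probe changed, only the measured background shares, gave the brightest class of probes E14.5 medians of −0.26 (MDE) and −0.25 (MDM). The observed medians of that class were −0.44 and −0.41, so this part may be large. Thinning left 103% in MDM and 70.2% in MDE. It keeps each probe's expected share of counts, so it cannot test an effect of depth on those shares. The 70.2% need not come from the number of counts alone, since fewer MDE probes entered the thinned fit. Of those called, 641 of 681 lower and 13 of 116 higher probes remained. Their medians both moved upward, from −1.0023 to −0.70345 and from 1.0053 to 1.4976. Whether the smaller set of probes shifted the scaling was not tested. Depth separates the genotypes at E14.5 in both regions. It also separated them in E13.5 MDM, with 2481026 to 3275877 counts in null and 1039606 to 1539942 in wild-type. There 0 probes passed and the brightest class had a median of 0.02, so a separation in depth did not by itself bring the pattern. Within E14.5 null MDM, though, the share on the brightest probes fell with depth, from 18.4% at 3707769 counts to 13.9% at 12379529. Depth therefore stays open as a cause in both regions. A change brought by the genotype itself, in tissue state or in transcription, also stays open and untested in both. A signal contrast that also varies between embryos of one group cannot be told apart from genotype, since null and wild-type libraries separate on it at E14.5: slopes from the E13.5 groups alone predicted 82.2% of the lower median in MDE and 96.0% in MDM, partly by how contrast is defined (61.7% and 91.5% outside the brightest probes), and contrast as a covariate moved it from −0.99 (SE 0.267) to −0.46 (SE 0.448) and from −0.52 (SE 0.127) to −0.17 (SE 0.218), where nearly all calls ended as estimates shrank and errors grew. Of the probes called higher, the 116 in MDE had a median of 1.17 (SE 0.364) against 0.42 predicted (35.9%) and 0.96 (SE 0.694) with the covariate, the 2443 in MDM had 0.37 against 0.31 predicted (83.1%) and 0.19 with the covariate, and r between predicted and observed across all probes was 0.345 in MDE and 0.688 in MDM.

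The low level of RTS0066123 in E13.5 null embryos is a narrower pattern. A signal contrast that also varies between embryos of one group is argued against, since the groups hardly differed in it (22.8% against 22.9% of counts on the brightest probes), which predicts a log2 fold change of −0.00208 (SE 0.0149) from the probe's slope inside the groups, against −1.87 (SE 0.322) observed; as a covariate, balanced as it was, it left −1.82 (SE 0.475), and the call ended because the error grew. A level set by single embryos and not by genotype cannot be told apart from a genotype effect. Every E13.5 null library lay below every wild-type library of its region (187, 880 and 553 against 2181, 1431 and 2388 CPM in MDE, and 116, 676 and 460 against 1374, 1580 and 2187 in MDM). For a probe fixed beforehand chance gives this in 10% of splits of 3 against 3. This probe was chosen by the lowest p of 14758 in MDE, so the 10% is no chance level for it. The MDM libraries come from the same embryos and are no independent check. Without null E13.5 replicate 1 the fold change in MDE was −1.49 (SE 0.395, adjusted p = 0.307), and null E14.5 replicate 2 was also low, at 814 CPM in MDE and 522 in MDM. Over 17 alternatives the adjusted p ran from 1.60e-09 to 0.9999, with 12 past the threshold. A genotype effect before fusion may therefore exist in this probe, but 3 embryos per group leave it open.

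RTS0068500 rose in wild-type mesenchyme between the stages and was lower in null than in wild-type mesenchyme at E14.5. Thinning left a log2 fold change of −2.12 against −2.15, but it keeps each probe's expected share of counts, so a difference in depth between the groups stays open. With signal contrast as a covariate −2.02 (SE 0.463) was left, and the call ended because the error had grown from 0.164. The covariate cannot decide on contrast here, since null and wild-type libraries separate on it at E14.5. The probe also lay near background in the other MDM groups, where its level can hardly vary with contrast. It stood there at 1.41 times background in null at both stages and at 1.26 times in E13.5 wild-type. The call held in 17 of 18 alternatives, with adjusted p from 4.80e-29 to 0.261. The rise in wild-type embryos passed with the covariate (2.43, adjusted p = 0.00846), but the interaction of genotype and stage was −2.36 (SE 0.274) without it and −2.23 (SE 0.550, adjusted p = 0.301) with it, 0 of the 2080 MDM interaction calls passed with it, and 5 of 100 splits gave as many calls. Loss of a stage-dependent rise in null mesenchyme may be a hypothesis to follow, found and tested on the same libraries, with the null level near background and the gene behind the probe not known here.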

How the results depend on the processing

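The contrast covariate, the thinned counts and the limma fits on background-subtracted signal were chosen after the results had been seen; the other alternatives were planned. Of 164 alternatives to the 15 counts of calls, not counting left-out libraries, 81 lay within 1.5 times and 83 did not. Over 59 results for named probes, 1076 alternatives gave 919 on the same side of the threshold, 150 that lost the call, 7 that gained it and 0 that changed sign; with upper-quartile scaling 59 of 59 stayed on their side, with the contrast covariate 26 of 59 lost it, and with a library left out 72 of 474 did. The cause of each difference below was not tested. Fewer counts, and in MDE fewer probes, entered the thinned fits. Fewer libraries entered the left-out fits, and fewer probes the limma fits with or without background subtraction. The filter at the limit of quantitation, the gene list tests and the check of Wnt7a and Hoxa13 were not run. Depth limits MDE most: in simulation 31% of 2-fold changes were recovered at E14.5 in MDE and 100% in MDM.

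With DESeq2 the counts were 0 for MDE at E13.5 (252 unadjusted), 281 for the MDE interaction with stage, 287 for the MDE average over stages, 33 for the MDE wild-type stage difference, 1704 for the MDM average, 110 for the MDM wild-type stage difference and 1 for genotype by region. With limma-voom they were 2, 1338, 351, 658, 484 and 67 for MDE at E13.5, at E14.5, the interaction, the null stage difference, the average and the wild-type stage difference, 2, 2689, 1199 and 1373 for MDM at E13.5, at E14.5, the interaction and the null stage difference, and 299 and 3 for the null region difference and genotype by region. With upper-quartile scaling they were 32 for the MDE wild-type and 5528 for the MDM null stage difference. With no low-count filter the MDE wild-type stage difference gave 8. With only the 6 libraries compared, the MDE wild-type stage difference gave 81, MDM at E13.5 2 and the MDM wild-type stage difference 175.

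With the contrast covariate edgeR gave 0 for MDE at E13.5, 0 at E14.5 and 0 for the interaction (693, 845 and 834 unadjusted), 40 and 11 for the null and wild-type stage differences and 2 for the average; in MDM 1, 5, 0 (1830 unadjusted), 516, 37 and 8 in that order; and 33 and 187 for the null and wild-type region differences. Thinned to the lowest total, MDE gave 190 at E14.5, 26 for the interaction, 88 for the null stage difference and 30 for the average, MDM gave 1 at E13.5, 2375 at E14.5, 971, 1477 and 625, and the regions gave 104 in null, 246 in wild-type and 3 for genotype by region. With MDM thinned to the embryo's MDE total, MDM gave 1 at E13.5, 1021 at E14.5, 157 for the interaction, 424 and 17 for the null and wild-type stage differences and 150 for the average. On background-subtracted signal limma gave 2, 306, 97 and 94 for MDE at E13.5, at E14.5, the interaction and the wild-type stage difference, 2639, 1856 and 156 for MDM at E14.5 and the null and wild-type stage differences, 395 for the null region difference and 3 for genotype by region. On the same probes without subtraction it gave 0 (616 unadjusted), 364, 27, 131 and 23 for MDE at E13.5, at E14.5, the interaction, the null stage difference and the average, 2689, 1775 and 137 for MDM at E14.5 and the null and wild-type stage differences, and 305 and 3 for the null region difference and genotype by region.

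The replicate numbers do not pair the samples across groups: deviations of samples with the same number had a median r of −0.0131 in MDE, with 1 of 18 above 0.1, and 0.00716 in MDM, with 4 of 18. With the replicate block MDE gave 2 at E13.5, 23 for the interaction, 18 for the average and 12 for the wild-type stage difference, and every other count with it was within 1.5 times. With no replicate block for the embryo, the region differences gave 321 in wild-type, 209 in null and 3 for genotype by region.

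Leaving out 1 library, in the order E13.5, E14.5, average, wild-type stage, null stage and interaction, MDE counts ranged from 0 (without null E13.5 replicate 1, 811 unadjusted) to 6 (null E13.5 replicate 3), 316 (null E14.5 replicate 3) to 706 (null E14.5 replicate 1), 3 (wild-type E14.5 replicate 3) to 110 (null E13.5 replicate 2), 3 (wild-type E13.5 replicate 1) to 31 (wild-type E13.5 replicate 3), 88 (null E13.5 replicate 2) to 575 (null E13.5 replicate 3), and 0 (wild-type E13.5 replicates 1 and 2, 1348 and 1577 unadjusted) to 394 (null E13.5 replicate 3). In the same order MDM counts ranged from 0 (677 unadjusted without wild-type E13.5 replicate 1) to 1 (null E13.5 replicate 2), 3966 (null E14.5 replicate 2) to 6019 (null E14.5 replicate 1), 275 (wild-type E13.5 replicate 3) to 2133 (null E13.5 replicate 2), 8 (wild-type E13.5 replicate 2) to 190 (wild-type E13.5 replicate 3), 1770 (null E13.5 replicate 2) to 5013 (null E13.5 replicate 3), and 720 (wild-type E13.5 replicate 2) to 3530 (null E13.5 replicate 3). Leaving out 1 embryo, the region differences ranged from 474 to 555 in wild-type and from 336 (null E14.5 replicate 2) to 616 (null E14.5 replicate 1) in null, and genotype by region from 2 (null E13.5 replicate 3) to 23 (null E13.5 replicate 1). Without null E14.5 MDE replicate 2, the library of MDM-like depth, MDE at E14.5 gave 509.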

Other observations

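The tests of signal contrast between regions were chosen after the data were seen, while the counts of other splits were planned.

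Signal contrast went with the embryo in both regions. Across the 12 embryos the share of counts on the brightest probes in MDE and in MDM correlated with Pearson's r = 0.98844 and Spearman's rho = 0.993 (permutation p = 2e-05 each, the smallest that the resamples can give). Without the 2 embryos farthest from the median r was 0.98767, and within the 6 embryos of each stage it was 0.977 at E13.5 and 0.996 at E14.5 (exact permutation p = 0.00278 each). The MDE and MDM libraries of an embryo were of very different depth, 139017 to 2618342 against 1039606 to 12379529 counts. Within E13.5, where null and wild-type overlapped, the MDE share still ran from 17.9% to 27.4%.

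The null E14.5 MDE library of replicate 2 had the depth of an MDM library, with 2618342 counts and a sequencing saturation (the share of aligned reads that added no further count) of 95.8%, against 51.6% to 58.0% in the other 11 MDE libraries and 95.3% to 96.3% in MDM. On the second principal component, on which the lowest MDE library lay at 1.32 and the highest MDM library at −0.77, it lay at 6.81, on the MDE side.

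Other splits of the libraries were counted for the remaining comparisons. With 6 libraries in 2 groups of 3 there are 10 splits, too few for a share under 0.05. In MDE the real split gave 1 call at E13.5 with 19 as the highest other (8 splits as large), 797 at E14.5 with 0, 21 for the wild-type stage difference with 4, and 288 for the null stage difference with 1 (1 split as large in each of these 3). In MDM it gave 0 at E13.5 with 1186 as the highest other (10 splits as large), 6001 at E14.5 with 0, 61 for the wild-type stage difference with 0, and 3619 for the null stage difference with 17 (1 split as large in each of these 3). The 1186 calls of another split of the E13.5 MDM libraries point to a structure among those 6 libraries that does not follow genotype. For the averages over both stages 5 of 100 splits gave as many calls as the 55 in MDE, with 434 as the highest other, and 6 of 100 as many as the 1057 in MDM, with 3817, so chance is not excluded. For the region differences 1 of 32 splits gave as many as the real 676 in wild-type, with 74 as the highest other, and 1 of 32 as many as the 644 in null, with 17. Chance is therefore excluded at 0.05 for these counts, without adjustment over the counts tested. Depth, which goes with region, is not excluded by these splits.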
